A study of Arabidopsis thaliana with 12 samples.

How the data were processed

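The measurements were gene expression profiles of rosette leaves of wild-type Arabidopsis thaliana (ecotype Columbia), made by hybridising biotin-labelled RNA to the Affymetrix ATH1 array, which reads 22810 probe sets. There were 12 arrays, 1 per plant, in 4 groups of 3 plants. Per the labels' protocols, plants aged 7 weeks were kept for 72 h in constant light at 24 °C and then treated for 150 min. One group stayed outside the exposure chamber in air with less than 0.08 ppm formaldehyde. The other groups were placed in the chamber and ventilated with clean air (less than 0.04 ppm), with 1 to 2 ppm formaldehyde (low exposure) or with 14 to 16 ppm formaldehyde (high exposure). About 100 mg of leaf per plant was frozen for RNA extraction. Per the labels' protocols, the 3 plants of a condition were in the chamber together, so chamber run and group cannot be told apart, and every p-value measures the spread between plants of a single run.

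The deposited values are log2 expression values per probe set, which the authors had background-corrected and normalized with GCRMA, per the submitters' processing notes. The options and the version of GCRMA are not given in the sources used here, and the log2 scale was inferred from the range of the values. All arrays share a lowest value of 2.11, and between 26.3% and 28.3% of the values on each array lie at it. At such probe sets the signal was not above background, and a difference against it is only a lower bound. The number of arrays, 3 per group, limits the precision. No 2 arrays held identical values, and arrays of a group correlated across probe sets at r between 0.956 and 0.989.

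A linear model with the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The 64 control probe sets were left out, and a probe set was tested if its log2 value was above 4 on at least 3 of the 12 arrays, which left 13874 of 22746 probe sets. The 4 comparisons were high exposure with clean air, low exposure with clean air, high with low exposure, and clean air with the outside of the chamber. A change was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of single genes are limma's. Differences are log2 values with the standard error (SE) of the fit, and group levels are means with the SD of 3 plants. Where all 3 arrays of a group were at or below 4, the fold change is given as "at least" a value computed from the level 4. Simulated data used each probe set's mean and its spread as moderated by eBayes, not its own residual spread. A 2-fold change, given to probe sets with a mean above 6, was recovered for between 61% and 68% of them and a log2 change of 2 for between 93% and 95%. There were 6 to 13 false calls among 13874 probe sets per comparison. Only 100 probe sets were changed at each size, with independent noise. The adjusted p cutoff is looser where many more probe sets change, so these figures do not describe the comparisons with low or high exposure. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

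Probe sets were named through a table of the array's gene annotation, with symbols updated by gene identifier through the RefSeq annotation of the assembly TAIR10.1. That table lists 14016 of the 22810 probe sets, 13513 with 1 gene (13436 of them matched by gene identifier) and 503 with several, and probe sets with several genes or none were not named. Its coverage is uneven: it holds 1552 of 10871 genes with a symbol of their own (14.3%) and 12630 of 27028 genes known by locus alone (46.7%). Well-characterised genes are therefore under-represented among the named genes, and of the 100 probe sets with the largest change in high exposure 44 could be named. The genes HOT5 (glutathione-dependent formaldehyde dehydrogenase), SFGH and SHM1 had no named probe set and were not analysed here.

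Genes were named by a rule set before the data were examined. For high exposure against clean air it takes the 10 largest rises and the 10 largest falls among called probe sets of a single gene whose 3 arrays in a group all lay above the 3 of the other, and for each other comparison 5 and 5. It adds up to 4 called members of each gene list described, or up to 2 members as values where none was called, and the gene FDH throughout. It stops at 25 list members per comparison, and those named beyond that number, so that each list has its result, were chosen after their values were seen. The rankings hold among named probe sets only and were made on the deposited values, so genes with values below 4 have no exact rank. The 25 gene lists, with 533 members, were also set beforehand. They cover formaldehyde and one-carbon metabolism, heat shock, the unfolded protein response, detoxification, antioxidants, sulfur assimilation, jasmonate, salicylic acid, ethylene, abscisic acid, touch, photosynthesis, the circadian clock, DNA repair, the proteasome, low oxygen, auxin, sugar starvation, phenylpropanoids, glucosinolates, and markers of guard cells, vasculature, trichomes, dividing cells and roots. Only 84 members (15.8%) had a named probe set, mainly because of the uneven naming, so a list result describes those members and not the pathway. Each gene was represented by its probe set with the highest mean. Lists with fewer than 3 tested members were not tested, a limit chosen after the data were seen, which left 10 lists and 40 tests.

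Lists were tested with limma's camera at a preset correlation of 0.01, in both directions, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation none of the list calls passed, and that adjusted p is given beside each. In simulations, a list of 9 uncorrelated genes shifted by a log2 of 1 had an unadjusted p under 0.05 in 100 of 100 draws and an unshifted list in 4 of 100. Alternatives tried were other filters, quantile normalization, median centring, other variance models, array weights, fits of 6 arrays, the replicate number as a block, plants outside the chamber as the control, a minimum fold of 1.2, fry in place of camera, and leaving out each array in turn. Fry asks whether the genes of a list change at all, and camera whether they change more than other genes. Passing fry therefore does not answer camera's question.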

Results

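The expression profiles of 12 leaf samples were compared to ask which transcripts differ in Arabidopsis leaves after 150 min in gaseous formaldehyde at 1 to 2 ppm or 14 to 16 ppm. Clean air in the same chamber served as the control. Plants outside the chamber were a further reference, and chamber, run and air cannot be told apart in that comparison. Each of the 4 groups held 3 plants. The median log2 signal per array lay between 5.72 and 5.90. The arrays differed in several control measures, of which 2 are given here. The 3' minus 5' signal of actin, GAPDH and ubiquitin control probe sets, which rises as RNA is degraded, averaged 1.12 ± 0.04 outside the chamber, 1.21 ± 0.05 in clean air, 1.47 ± 0.05 at low exposure and 1.60 ± 0.21 at high exposure (log2, SD, n = 3). The bioC spike-in controls averaged 8.78 ± 0.13 at low exposure against 6.53 ± 0.26 in clean air, 6.99 ± 0.21 outside and 7.23 ± 0.23 at high exposure.

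**Figure D1:**
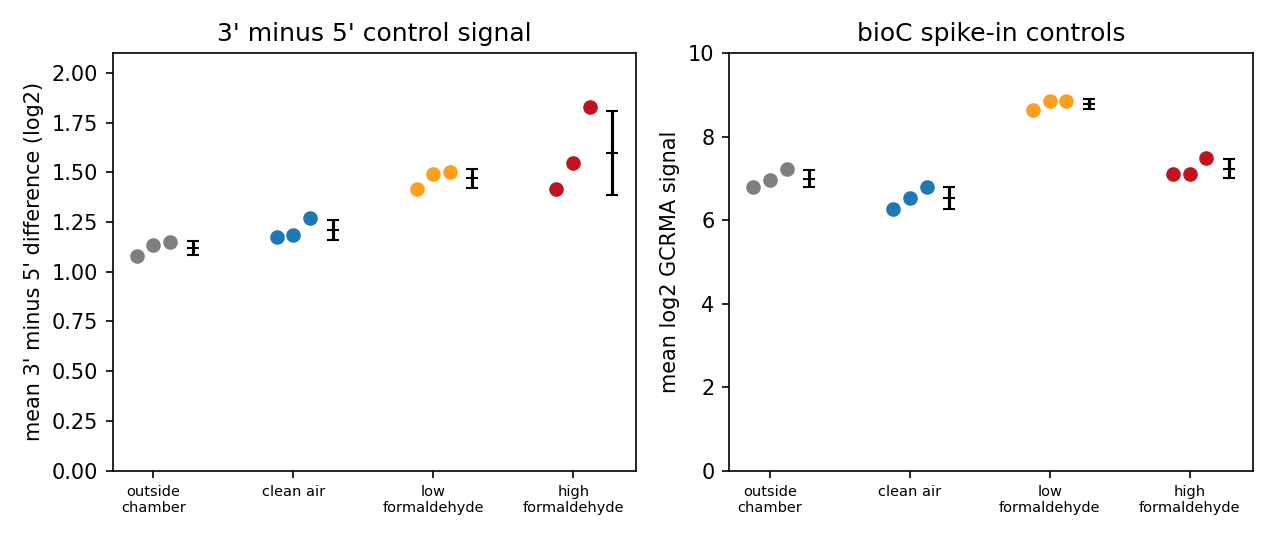
Control measures per array in the 4 groups, as log2 values: the mean 3' minus 5' difference of control probe sets (left) and the mean bioC spike-in signal (right). Points are arrays, and the bars beside them the mean and SD of 3 arrays; the bioC signal averaged 8.78 at low exposure and 6.53 in clean air.

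High exposure was compared with clean air first. Genes of small heat shock proteins, which bind unfolding proteins, were among the largest rises. AT5G51440, a mitochondrial small heat shock protein (HSP23.5), went from 2.18 ± 0.04 to 13.55 ± 0.07 (log2, SD, n = 3), at least 749-fold (adjusted p = 2.58e-11). The cytosolic small heat shock proteins AT2G29500 (HSP17.6B) and AT1G53540 (HSP17.6C) rose at least 347-fold and at least 171-fold, and Hop3, a co-chaperone, rose at least 99.0-fold. Without replicate 1 of high exposure the bound of AT1G53540 was 306-fold. Of the heat shock list 9 members had a named probe set. The 2 with too few arrays above 4, ATHSP22.0 and HSA32, were not tested, and 4 of the 7 tested were above 4 at high exposure alone, so their testing itself depended on the rise. These 7 rose, with a mean log2 difference of 7.65 and a mean of 6.75 with 4 members at their bound. The list passed camera (adjusted p = 3.34e-08), with an adjusted p = 0.0752 with an estimated correlation. All 7 were also called adjusted over the list alone.

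The tested members of the detoxification list rose in the same arrays. The 6 tested members of the xenobiotic and electrophile list rose (3 of them above 4 at high exposure alone), by a mean log2 of 6.42, or 5.48 with 3 members at their bound (camera adjusted p = 4.39e-08; adjusted p = 0.0752 with an estimated correlation). The MATE transporter gene AT2G04050 rose at least 61.1-fold and its relative AT2G04070 by 6.31 ± 0.31 (log2, SE). The glutathione transferase gene GSTU25 rose at least 28.5-fold (46.1-fold without replicate 1 of high exposure), and the glycosyltransferase gene UGT73B5 rose from 4.49 ± 0.23 to 11.43 ± 0.22. All 6 were called adjusted over the list alone. Their wider gene families did not rise as a whole. Of 5 tested genes with the symbol stem GSTU 1 rose and 4 fell, and of 25 with the stem UGT 9 rose and 11 fell. The 3 tested members of the list of antioxidant enzymes and reactive oxygen markers (the antioxidant list) also rose. Their mean was 4.24 (camera adjusted p = 0.00743, and adjusted p = 0.145 with an estimated correlation). No antioxidant enzyme of the list had a named probe set, and the 3 were not such enzymes. They were AT2G21640, a marker of oxidative stress (log2 7.47 ± 0.24), NDB2, an external mitochondrial NAD(P)H dehydrogenase (2.77 ± 0.44), and STZ, a zinc finger repressor (2.46 ± 0.58; 3.18 without replicate 3 of clean air), and the 3 were called adjusted over the list alone.

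**Figure D2:**
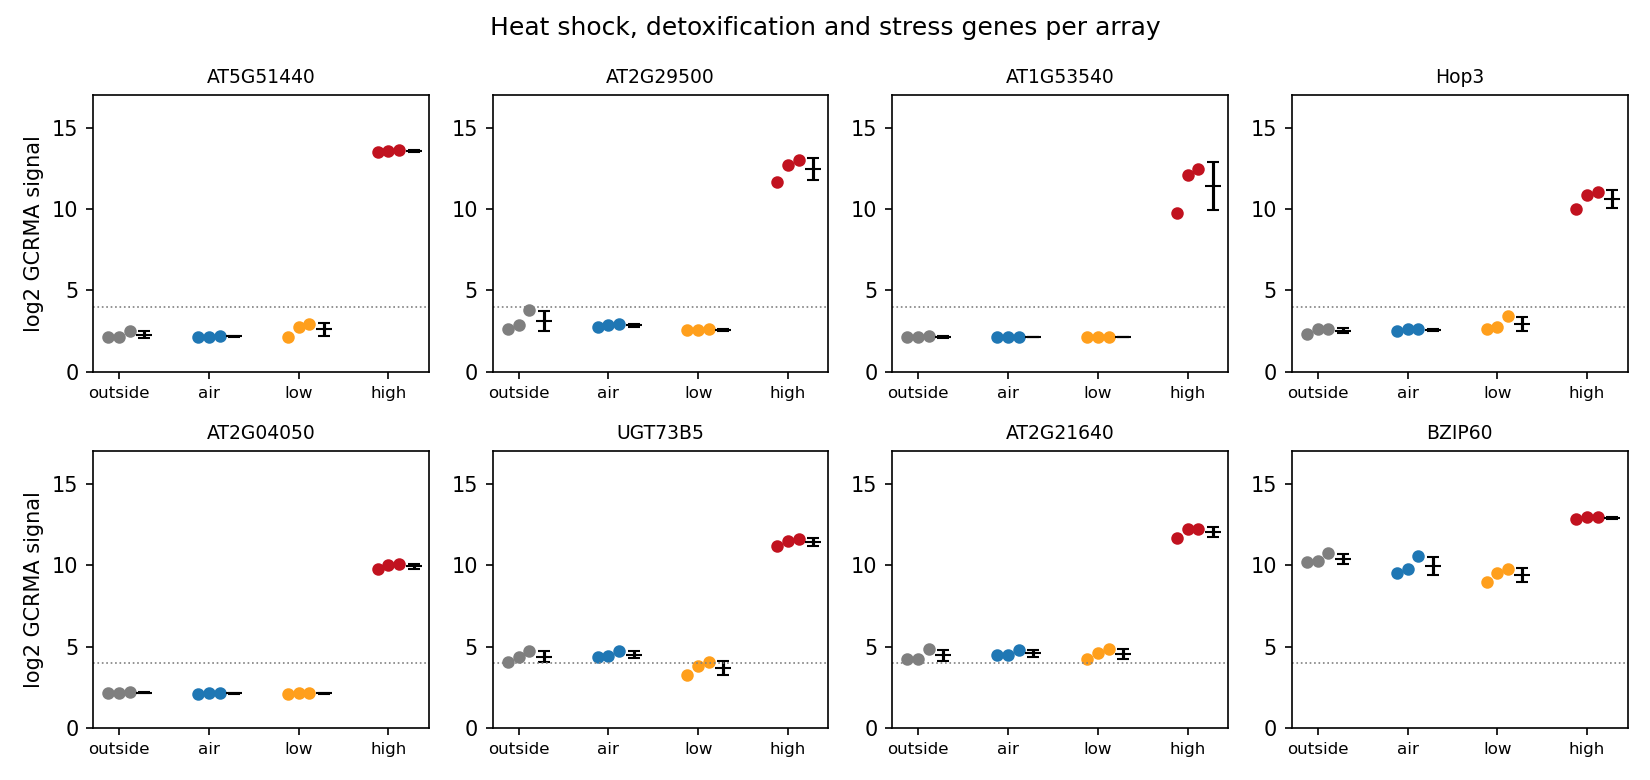
Log2 GCRMA signal of 8 genes on each array, by group (outside chamber, clean air, low and high formaldehyde). Points are arrays, bars the mean and SD of 3 arrays, and the dotted line the level 4 above which a probe set counted as measured; AT5G51440 averaged 13.55 at high exposure and 2.18 in clean air.

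In the unfolded protein response list 3 of 4 tested members rose (mean 1.28, camera adjusted p = 0.026; adjusted p = 0.145 with an estimated correlation). The transcription factor genes BZIP60 and BZIP28 rose by 2.97 ± 0.27 and 1.28 ± 0.19 and DER1 by 0.97 ± 0.14 (log2, SE), the same number adjusted over the list alone. In the touch and rapid stress list 6 of 7 rose (mean 2.97, camera adjusted p = 0.0128; adjusted p = 0.256 with an estimated correlation), as did 6 adjusted over the list alone. The calmodulin-like genes CML37 and CML38 rose, CML37 by 4.13 with values below 4 raised to 4 and CML38 by 5.02 ± 1.38, the transcription factor gene WRKY6 by 3.17 ± 0.33 and the ubiquitin ligase gene PUB23 by 3.23 ± 1.22. Without replicate 3 of clean air, where both calmodulin-like genes were high, CML37 rose at least 45.0-fold, as both other clean-air arrays were below 4, and CML38 by 6.84. The call of PUB23 was lost in 10 of the 12 fits that each left out 1 array (all but those without replicate 3 of clean air or of low exposure), with log2 values of 1.89 to 4.98 and adjusted p up to 0.169.

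Other large rises lay outside the lists. AT5G14730 rose at least 305-fold, AT2G41730 from 5.45 ± 0.53 to 14.42 ± 0.12, and AT1G71000, a gene for a DnaJ-domain protein, at least 133-fold. AT2G32020 rose at least 56.7-fold and UGT73C1, a glycosyltransferase gene, at least 50.4-fold (each adjusted p at most 3.35e-08).

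Among the largest falls were TBL26, a gene of the trichome birefringence-like family, which was at least 47.8-fold lower, and JAL23, a jacalin-related lectin gene. AT1G47400, which encodes a peptide of the iron deficiency response (IMA1), was at least 23.8-fold lower (15.8-fold without replicate 3 of clean air), AT1G01320 at least 21.7-fold and AT5G05250 at least 25.2-fold. The sugar transporter gene SWEET13 was at 3.06 ± 0.29 against 8.15 ± 0.92 (log2, SD), and the sucrose phosphate synthase gene ATSPS4F fell by 4.28 (SE 0.86). AT1G68600 was 36.8-fold lower, AT3G28270 was at 3.51 ± 0.87 against 8.57 ± 0.79 (log2, SD), and AT2G15020 fell by 4.33 (SE 0.73). Without replicate 1 of high exposure ATSPS4F fell by 3.59 and AT2G15020 by 3.49. JAL23 and AT3G28270 averaged under 4 at high exposure, and with values below 4 raised to 4 they fell by 4.98 and 4.53. In the arrays of these falls the 3' minus 5' control signal was also higher, 1.60 ± 0.21 against 1.21 ± 0.05.

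Of the formaldehyde and one-carbon metabolism list 5 of 9 tested members fell and none rose, with the same 5 of 9 adjusted over the list alone, and the list did not pass camera (mean -0.63, adjusted p = 0.0752; adjusted p = 0.18 with an estimated correlation). It passed without replicate 1 of clean air (adjusted p = 0.049), without a filter and with fry (adjusted p = 0.000106). AT1G11860, the glycine decarboxylase T-protein, was at 11.93 ± 0.24 against 13.03 ± 0.11 (log2, SD; adjusted p = 0.00329). On the log2 scale 5-FCL, a folate cyclo-ligase, fell by 1.02 ± 0.19 (SE), and AT5G47435 and AT4G17360, both formyltetrahydrofolate deformylases, fell by 0.89 ± 0.14 and 0.79 ± 0.28. The last call was lost without replicate 2 or 3 of clean air or replicate 2 of high exposure (adjusted p up to 0.129). FDH, formate dehydrogenase, was at 11.71 ± 0.18 and 12.65 ± 0.67 and did not pass (log2 difference -0.94, adjusted p = 0.087), but passed without replicate 1 of clean air (log2 difference -1.33) or replicate 3 of low exposure (adjusted p = 0.023), with array weights, from the 6 arrays alone, with spike-in scaling and without the low arrays.

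Among photosynthesis genes 4 of 10 tested members fell, the same number adjusted over the list alone, and the list did not pass camera (mean -0.39, adjusted p = 0.111; adjusted p = 0.405 with an estimated correlation), though it passed fry (adjusted p = 0.00116). The Calvin cycle enzyme genes SBPASE and PRK fell by 1.35 ± 0.22 and 1.14 ± 0.18 and the ATP synthase gene ATPC1 by 0.61 ± 0.08. RCA, rubisco activase, fell by 0.26 ± 0.08, a call lost without replicate 1 of clean air or of high exposure (adjusted p up to 0.0819), and also under 7 other settings, among them quantile normalization and spike-in scaling. Members of the light-harvesting and photosystem proteins did not pass.

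The lists of sulfur assimilation, auxin and abscisic acid did not pass camera either (adjusted p = 0.176 for sulfur assimilation, 0.477 for auxin and 0.259 for abscisic acid). Of 5 sulfur assimilation genes GR1, a glutathione reductase, fell by 0.73 ± 0.20 (log2, SE; also 1 adjusted over the list alone). Of 4 auxin genes IAA29 and the expansin gene EXPA8 fell by 3.93 ± 0.94 and 2.19 ± 0.37 (with values below 4 raised to 4 IAA29 fell by 3.48, and without replicate 2 of clean air it fell by 2.51), with 2 falls and 1 rise adjusted over the list alone. Of 4 abscisic acid, drought and cold genes only LTI30, a dehydrin gene, passed (2.23 ± 0.83), with 0 adjusted over the list alone. Its call held in 4 of 12 fits without 1 array, those without an outside replicate or without replicate 3 of clean air, and adjusted p reached 0.135. Among single members of lists too small to test, GRX480, a glutaredoxin gene of salicylic acid signalling, rose by 6.02 ± 0.91 (with values below 4 raised to 4 by 5.73, and by 6.60 without replicate 3 of clean air) and SAG101 by 0.88 ± 0.25. BCAT4, of methionine-derived glucosinolate synthesis, fell by 3.15 ± 0.38, and UGT78D2 by 0.91 ± 0.28. JMT was at least 1.29-fold lower. The call of UGT78D2 was lost without replicate 1 or 3 of clean air or replicate 2 of high exposure (adjusted p up to 0.0595). That of JMT was lost without any 1 clean-air replicate or replicate 1 or 2 of high exposure (up to 0.124) and against plants outside the chamber, and that of SAG101 with spike-in scaling. The ethylene genes EIN3 and RTE1 (0.10 and -0.14), the clock gene GI (0.84), the DNA repair gene AT1G48360 (-0.41), the proteasome gene RPN12a (-0.09), and the defensin gene PDF1.2 (0.02) did not pass (log2 differences), and no low oxygen gene was tested. AT1G48360 passed with array weights and with spike-in scaling, and RTE1 against plants outside the chamber. PDF1.2 varied widely between plants, at 4.04, 6.67 and 9.99 at high exposure and 6.67, 5.86 and 8.11 in clean air (log2). Of the cell type markers, TRY of trichomes was at least 2.52-fold lower, SWEET11 of phloem fell by 0.78 ± 0.23, a call lost without replicate 2 or 3 of high exposure (adjusted p up to 0.054), FMA of guard cells (-0.42; adjusted p = 0.0315 without replicate 1 of high exposure, and passing also with array weights) did not pass, AUR1 of dividing cells was not above 4 in either group, and root markers were not tested.

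Over all probe sets, 7337 of 13874 changed (52.9%), 3157 up and 4180 down, of which 1784 and 2255 by at least 2-fold. The share that rose, 43.0%, was 29.9% when arrays were scaled to the bioB, bioD and cre spike-in controls, a scaling that moves the median difference of all probe sets from -0.10 to -0.32.

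**Figure D3:**
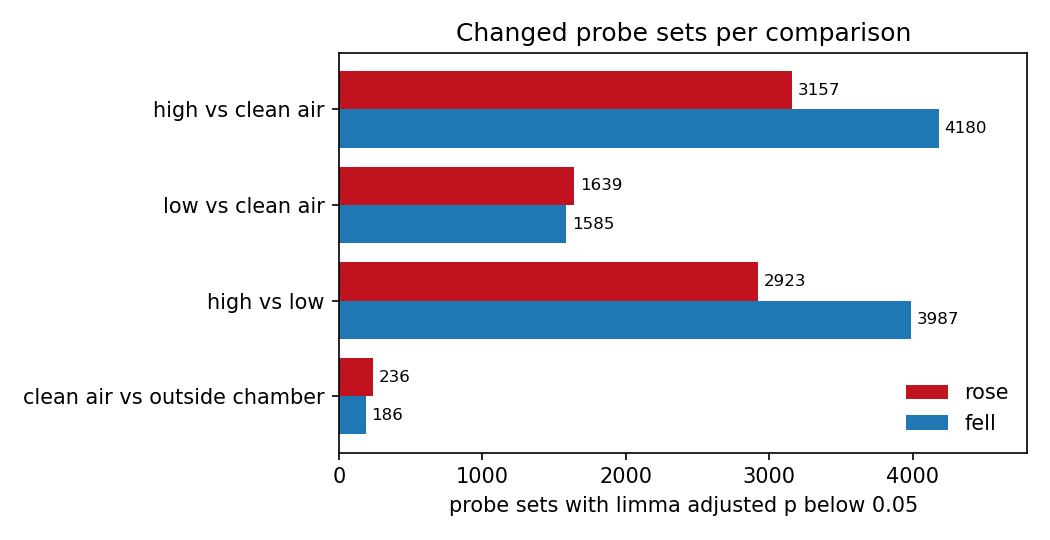
Number of probe sets that rose or fell in each comparison (limma, adjusted p below 0.05, of 13874 tested). Bars start at 0; 3157 rose and 4180 fell in high exposure against clean air, and 236 rose and 186 fell in clean air against the outside of the chamber.

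Low exposure was compared with clean air to see what 1 to 2 ppm changed. Among the largest rises were AT2G41990, at 8.77 ± 0.52 against 3.52 ± 2.00 in clean air (log2, SD), XTH16, a cell wall xyloglucan-modifying enzyme gene, at 7.89 ± 0.40 against 3.80 ± 1.11, AT4G21870 (log2 difference 3.92 ± 0.60, SE), AT4G29020 (3.67 ± 0.80) and ULT1 (3.55 ± 0.49). The first 2 averaged under 4 in clean air, so their differences are not exact: with values below 4 raised to 4 they were 4.16 and 3.62, and AT2G41990 rose at least 27.3-fold without replicate 1 of clean air, where the other 2 arrays were below 4. Among the largest falls were the lectin gene JAL23, at least 35.3-fold lower, AT1G76960 (fell by 5.27 ± 0.86), AT4G17470, at least 12.4-fold lower, AT4G01390 (fell by 4.70 ± 0.57) and ZW9 (fell by 4.61 ± 0.91). With plants outside the chamber as the control the call of AT4G29020 was lost (log2 1.67, adjusted p = 0.126). Without replicate 3 of clean air AT4G21870 rose by 3.05 and ULT1 by 2.94, and ZW9 fell by 3.75. AT4G01390 fell by 4.01 without replicate 3 of low exposure and AT1G76960 by 6.09 without replicate 1.

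No gene list passed camera at low exposure, 2 had an unadjusted p under 0.05, and 2 passed limma's fry. Of 7 heat shock genes, 4 of them not above 4 in either group, none rose, and AT2G20560, a DnaJ gene, fell by 1.31 ± 0.40 (2 members called adjusted over the list alone). Its call was lost without replicate 2 or 3 of clean air or of low exposure or replicate 2 of high exposure, with adjusted p up to 0.144. Of 6 detoxification genes, 3 of them not above 4 in either group, none rose, and UGT73B5 fell by 0.79 ± 0.25 (by 0.47 with values below 4 raised to 4), with 0 called adjusted over the list alone, a call lost in 8 of 12 fits without 1 array (adjusted p up to 0.144), those without any clean-air replicate among them. Of 9 one-carbon genes 3 fell and 1 rose, with 4 called adjusted over the list alone: AT3G12290 fell by 0.61 ± 0.14, 5-FCL by 0.76 ± 0.19 and ALDH7B4 by 1.36 ± 0.44, and AT5G47435 rose by 0.45 ± 0.14. The call of 5-FCL was lost without replicate 3 of clean air (adjusted p = 0.0682). Those of ALDH7B4 and AT5G47435 were each lost in 9 of 12 fits (adjusted p up to 0.174 and 0.165), among them those without replicate 2 or 3 of clean air and each of the 3 without a high exposure replicate. With spike-in scaling the calls of AT3G12290, AT5G47435, UGT73B5 and APS3 were lost. FDH did not pass (-0.78, adjusted p = 0.211). The sulfur assimilation genes APS4 and APS3, both ATP sulfurylases, fell by 0.98 ± 0.19 and 0.72 ± 0.21 (2 adjusted over the list alone). The call of APS3 was lost without replicate 1 or 3 of clean air or 1 or 2 of low exposure (adjusted p up to 0.0999). Of 4 cold genes COR15A fell by 3.28 ± 0.77 (4.06 without replicate 1 of clean air), a call lost without replicate 2 or 3 of clean air (adjusted p up to 0.0552), and 4 were called adjusted over the list alone. The list itself passed camera without replicate 2 of the outside group or replicate 1 of clean air (adjusted p down to 0.0314). BCAT4 fell by 2.04 ± 0.38, and SAG101 by 0.93 ± 0.25, and JMT was at least 1.29-fold lower. The call of SAG101 was lost without replicate 2 or 3 of clean air or of low exposure (adjusted p up to 0.0775), and that of JMT in these 4 fits and without replicate 1 of low exposure (up to 0.112) and against plants outside the chamber. The marker AUR1 was at least 1.58-fold higher. The antioxidant, unfolded protein, touch, photosynthesis and auxin lists held no called member (auxin 1 rise and 1 fall adjusted over the list alone), and camera gave adjusted p-values from 0.292 upward for these 5, and 0.126 for the cold list, the lowest of all. In the auxin list the mean was 0.09 and the median -0.25.

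Of all probe sets, 3224 of 13874 changed at low exposure (23.2%), 1639 up and 1585 down, of which 614 and 783 by at least 2-fold. The count was 1671 without replicate 2 of clean air and 1601 without replicate 3 of clean air, 4919 against plants outside the chamber, and 1594 with 30.3% up when scaled to spike-in controls. The arrays of this group also stood apart in bioC signal (8.78 against 6.53).

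High exposure was compared with low exposure directly. AT5G51440, AT2G29500 and AT1G53540 were at least 749-fold, 347-fold and 171-fold higher, AT1G71000 at least 133-fold and AT2G04050 at least 61.1-fold. The iron peptide gene AT1G47400 was at least 60.9-fold lower, AT5G05250 at least 43.7-fold, AT4G25780 at least 6.99-fold and AT1G01320 at least 8.39-fold, and AT1G49200 fell by 3.73 ± 0.89 (SE). Without replicate 3 of low exposure the bounds of AT1G47400 and AT5G05250 were 21.6-fold and 27.3-fold. Without replicate 1 of high exposure AT1G53540 was at least 306-fold and CML37 at least 85.3-fold higher, and AT1G49200 fell by 4.71. The 7 heat shock, 6 detoxification and 3 antioxidant-list members tested rose (means 8.02, 6.52 and 4.55, and 7.20 and 5.58 with bounds for the first 2). None of the last 3 is an antioxidant enzyme. Camera gave adjusted p = 2.73e-09, 8.43e-09 and 0.00207, and adjusted p = 0.055, 0.055 and 0.105 with an estimated correlation. Of the touch list 6 of 7 rose (mean 3.63, or 3.39 with 1 member at its bound, camera adjusted p = 0.00207; adjusted p = 0.234 with an estimated correlation), with CML37 at least 45.0-fold and CML38 6.93 ± 1.38 higher, and of the unfolded protein list 3 of 4 (mean 1.68, camera adjusted p = 0.00451; adjusted p = 0.0718 with an estimated correlation), with BZIP60 higher by 3.52 ± 0.27. All of these were also called adjusted over the list alone.

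The 4 cold and drought genes were all higher at high than at low exposure (mean 3.67, camera adjusted p = 0.0114; adjusted p = 0.262 with an estimated correlation): COR15B by 4.42 ± 0.94 (3.52 without replicate 3 of low exposure), LTI30 by 4.39 ± 0.83, COR15A by 3.36 ± 0.77 and COR47 by 2.52 ± 0.56, all 4 also adjusted over the list alone. Photosynthesis genes were lower, 5 of 10 (mean -0.45, camera adjusted p = 0.0315; adjusted p = 0.3 with an estimated correlation), SBPASE by 1.46 ± 0.22, PRK by 1.12 ± 0.18, ATPC1 by 0.67 ± 0.08 and PSBY by 0.44 ± 0.10 on the log2 scale. The same 5 were called adjusted over the list alone. That list call was lost without replicate 1 of low exposure (adjusted p = 0.0697) and without replicate 1 of high exposure (adjusted p = 0.082). In the one-carbon list (camera adjusted p = 0.424) AT5G47435, AT1G11860 and AT4G17360 were lower by 1.34 ± 0.14, 1.25 ± 0.25 and 0.81 ± 0.28 and ALDH7B4 higher by 1.51 ± 0.44, and FDH did not pass (-0.16, adjusted p = 0.784). The call of AT4G17360 was lost without replicate 1 or 3 of low or 2 of high exposure (adjusted p up to 0.123), and that of ALDH7B4 without replicate 3 of low exposure (0.0593). In the sulfur list (mean -0.04, camera direction upward, adjusted p = 0.91) APS4 was higher by 0.65 ± 0.19 and GR lower by 0.72 ± 0.20, and in the auxin list (camera adjusted p = 0.516) EXPA8 and IAA29 were lower by 2.75 ± 0.37 and 2.87 ± 0.94. The call of APS4 was lost without replicate 2 or 3 of low exposure (adjusted p up to 0.052) and with spike-in scaling. In these 3 lists 3, 1 and 2 falls and 1, 1 and 1 rises were called adjusted over the list alone. The call of IAA29 was lost without replicate 1 or 2 of low or 2 or 3 of high exposure (adjusted p up to 0.0921), and with values below 4 raised to 4 it fell by 2.42, and fell by 3.43 without replicate 3 of low exposure.

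**Figure D4:**
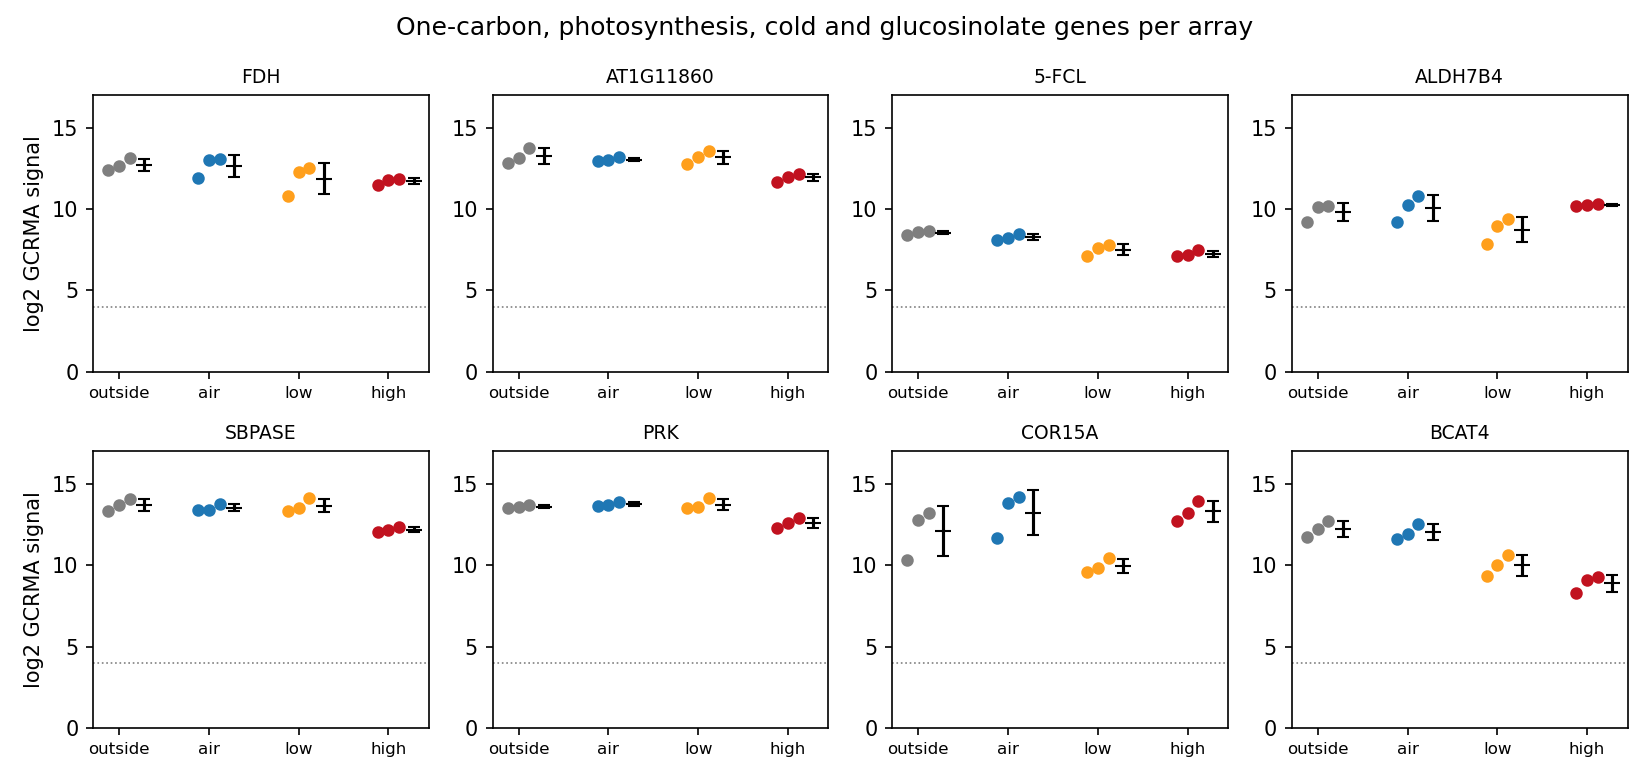
Log2 GCRMA signal of 8 genes of one-carbon metabolism, photosynthesis, cold response and glucosinolate synthesis on each array, by group. Points are arrays, bars the mean and SD of 3 arrays, and the dotted line the level 4; FDH averaged 11.71 at high exposure and 12.65 in clean air.

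Between the exposures 6910 of 13874 probe sets differed (49.8%), 2923 higher and 3987 lower at high exposure. The differences from clean air at low and high exposure correlated across probe sets at r = 0.389, with the same sign in 63.3% of them. Groups without any effect that share the clean-air arrays gave 0.4995 and 66.7% in 100 simulations. Sharing alone gives such values whatever the size of the noise, so they cannot show how much of the observed r and share it explains. The covariance, which does depend on the size of the differences, was 0.399 against 0.0452 in the simulations. The shared arrays alone thus gave a smaller covariance than the one observed. With no shared array r was 0.377 (high exposure against the outside) or 0.223 (low exposure against the outside). Both exposures raised 743 and lowered 1034 of the same probe sets, where independent lists give 373 and 477.5, and 145 and 121 moved in opposite directions, where they give 493.8 and 360.7. Both comparisons use the same 3 clean-air arrays, and probe sets are not independent replicates.

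Clean air in the chamber was compared with the outside of the chamber, 2 groups that differ in chamber, run and air together. RBL was at 6.46 in clean air and 3.94 outside (log2; 4.58-fold with values below 4 raised to 4). AT4G26600 rose at least 2.25-fold, AT3G06530 by 2.07 ± 0.47 (log2, SE) and AT1G79150 at least 1.92-fold, and AT3G52170 was at 5.07 ± 0.49 in clean air and 2.89 ± 0.52 outside (log2, SD). Among the largest falls were AT4G12490, at least 10.0-fold lower, SIS (fell by 3.64 ± 0.48), AT5G52390 (fell by 3.47 ± 0.58, or by 2.25 with values below 4 raised to 4), AT4G28140, at least 2.92-fold lower, and the expansin gene EXPA16 (fell by 3.41 ± 0.30). The call of AT3G06530 was lost in 9 of 12 fits without 1 array (adjusted p up to 0.123), all but those without outside replicate 3 or high exposure replicate 1 or 3. That of AT5G52390 was lost without outside replicate 2 or clean-air replicate 1 or 2 (up to 0.0635), and that of AT4G28140 without clean-air replicate 1 or 2 (up to 0.0676). Without replicate 2 of the outside group AT3G06530 rose by 1.41 and the bound of AT4G28140 was 1.51-fold. From the 6 arrays alone the calls of RBL, SIS, AT3G52170, AT5G52390, AT4G28140 and AT3G06530 were lost.

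No gene list passed camera here, with adjusted p-values from 0.0943 upward, 2 had an unadjusted p under 0.05, and 0 passed fry. Of the 7 tested members of the touch and rapid stress list, WRKY6 fell by 1.93 ± 0.33 (SE), with 2 falls adjusted over the list alone. The call of WRKY6 was lost without replicate 1 or 2 of clean air (adjusted p up to 0.0609) and from the 6 arrays alone. The touch genes TCH2, TCH3 and TCH4 of that list had no named probe set. That list passed without replicate 3 of the outside group or of clean air (adjusted p down to 0.000229), and the unfolded protein list without replicate 3 of the outside group (0.0423). The 9 one-carbon, 7 heat shock, 6 detoxification, 10 photosynthesis and 5 sulfur genes gave no call. Neither did the 4 auxin, 4 cold and 4 unfolded protein genes or the 3 members of the antioxidant list. Of the detoxification genes 3 were not above 4 in either group. Adjusted over the list alone 1 sulfur and 1 unfolded protein gene fell. FDH was at 12.65 ± 0.67 and 12.71 ± 0.36 (adjusted p = 0.955). The antioxidant mean was -0.03 with a median of 0.12. Of the heat shock genes 4 were not above 4 in either group, and the other 3 had a mean of 0.30 and a median of 0.19.

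In this comparison 422 of 13874 probe sets changed (3.04%), 236 up and 186 down. The count was 65 without replicate 2 and 91 without replicate 1 of clean air, 270, 149 and 221 without replicates 1, 2 and 3 of the outside group, 103 from the 6 arrays alone, and 1377 with 94.0% up when scaled to spike-in controls, which moves the median difference from 0.02 to 0.41.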

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

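The spike-in tests with the spread between arrays were chosen after the result was seen, and the other tests before. Control probe sets, which the comparisons leave out, carried differences between groups. The bioC spike-in probe sets were higher at low exposure than in clean air by 2.65, 2.13, 2.17 and 2.03 (log2). The 25S ribosomal RNA and a GAPDH 3' control probe set were higher at high exposure than in clean air by 1.06 and 1.07. Other GAPDH probe sets were higher too, by 0.83 (3'), 0.89 (middle), and 0.74 and 0.62 (5').

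The low exposure arrays stand apart in bioC, and bioB probe sets were also higher there than in clean air (by 0.69, 0.57 and 0.73 for the first 3), as they were outside the chamber (clean air minus outside -0.59, -0.54 and -0.51), while the median of the bioB, bioD and cre controls was 10.60 ± 0.21 against 10.51 ± 0.28 (SD, n = 3). A candidate explanation of the low exposure calls is a batch of these arrays alone. If that were the whole cause, the calls should not share their sign with high exposure set against the outside of the chamber, a comparison without shared arrays. They did for 76.1% of calls, and for 73.2% to 81.5% when each array was left out, which argues against a batch of the low arrays alone as the whole cause. A batch that the low and high arrays share would give the same signs, so this test cannot tell it from a response. It stays open, as do a batch that adds to a response, a difference in RNA integrity that low and high exposure share, and the exposure itself.

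More probe sets fell than rose at high exposure. A shift of the high arrays by normalization of 0.1 or more would have lowered the spike-in controls too. The median difference of 18 of them was 0.19 (95% bootstrap interval over probe sets 0.12 to 0.44), though a bioD (-0.08) and some cre probe sets (-0.05 and -0.08) were lower. That interval treats repeated probe sets of the same spike-in as independent and leaves out the spread between arrays. Of 4 versions of the test with that spread 1 excluded such a shift (0.48, interval -0.02 to 0.97) and 3 did not (0.24, -0.18 to 0.66; 0.22, -0.35 to 0.79; 0.16, -0.26 to 0.57), so the shift stays open. Lower RNA integrity may contribute: the 3' minus 5' control signal was higher on all 3 high arrays than on all 3 clean-air arrays, by 0.39 on average. The gap was widest for actin, whose 3' and 5' probe sets moved by 0.41 and -0.34 and by 0.27 and -0.48. They moved by 0.83 and 0.74 and by 1.07 and 0.62 for GAPDH, and by 0.19 and -0.02 and by 0.08 and 0.02 for ubiquitin. Integrity moved with the group, so it stays open beside a response of the leaves, and neither was tested further.

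Each comparison sets 3 arrays against 3, which makes 10 splits, too few for a share under 0.05. The real split, 1 of 10 to reach its count in each comparison, gave 7337, 3224, 6910 and 422 changed probe sets for high against clean air, low against clean air, high against low and clean air against outside, and the highest of the other splits gave 1, 1, 0 and 6. Each other split mixes plants of both groups, so a difference between the groups enters its residual spread and lowers its count. These counts are therefore no level of false calls, and a difference between chamber runs would give the same picture.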

How the results depend on the processing

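Settings chosen after the data were seen were the spike-in scaling, probe sets without a suffix letter, probe sets above 4 on all arrays, and the fit without the low arrays. The counts for high against clean air (7337) and high against low (6910) stayed within 1.5 times under every setting run, with 6111 to 7490 and 5558 to 7044 when each array was left out. The count for low against clean air (3224) was 4845 with array weights, 4919 with outside plants as the control, 1363 against a minimum fold of 1.2, 1594 with spike-in scaling (30.3% up against 50.8%), and 1601 to 3385 without 1 array. The count for clean air against outside (422) was 1188 with array weights, 186 without a filter (more tests), 103 from the 6 arrays (fewer arrays), 112 against a minimum fold of 1.2, 1377 with spike-in scaling (94.0% up against 55.9%), and 65 to 542 without 1 array. For high against clean air spike-in scaling gave 29.9% up against 43.0%. The cause of these moves was not tested.

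Of 40 list tests 12 passed, 0 with an estimated correlation, 18 with fry, 19 with fry's mixed test and 11 to 14 without 1 array. With an estimated correlation 7 had an unadjusted p under 0.05. The correlation between low and high differences (0.389) was 0.223 with outside plants as the control of low exposure, and 0.33 to 0.451 without 1 array. Of 50 calls of the largest rises and falls, 43 held under each setting in which their probe set was tested, and 7 were lost under at least 1. Stricter filters, and the filter applied anew without 1 array, removed some probe sets from testing. Those above 4 on the 3 high exposure arrays alone, such as AT5G51440, were not tested without any 1 of these arrays.

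With replicate block, the number as a block, 7208, 3121, 6810 and 346 probe sets were called (same order as above, clean air against outside last), and 12 lists. Replicate numbers did not pair the arrays: same-numbered arrays deviated together at r from -0.328 to 0.326, over 0.1 in 8 of 18 pairs, and differently numbered ones at -0.382 to 0.331, over 0.1 in 13 of 36.

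Directions turned in 36 values, of which 0 passed the test there or in the result reported. The 36 count fry's direction again for its mixed test, which has no direction of its own. For AUR1 at high against clean air the values were -0.049 with outside plants as the control, -0.028 with spike-in scaling and -0.065 to 0.33 without 1 array, all between groups not above 4, so these turns carry no information. EIN3 gave -0.11 with spike-in scaling, FMA 0.10 with outside plants, and RPN12a 0.052 with array weights and -0.19 to 0.038 without 1 array. FDH gave 0.33 with spike-in scaling and -0.28 to 0.32 without 1 array in clean air against outside, and -0.69 to 0.17 in high against low. Without 1 array, the list means ran from -0.37 to 0.96 (abscisic acid), -0.36 to 0.30 (antioxidant), -0.90 to 0.20 (auxin), -0.0050 to 0.30 (heat shock) and -0.081 to 0.032 (detoxification) in clean air against outside, from -0.57 to 0.0080 (antioxidant), -0.44 to 0.65 (auxin), -1.29 to 0.33 (touch) and -0.20 to -0.037 (detoxification) in low against clean air, and from -0.074 to 0.022 (sulfur) in high against low. With fry the direction was opposite to camera's for the antioxidant list in clean air against outside (mean -0.032, camera downward). The same held for the sulfur list in high against low (mean -0.040, camera upward). The heat shock and detoxification means above include members not above 4 in either group, except in fits without a high exposure array. Those fits no longer tested the members above 4 at high exposure alone. The ends 0.30 (heat shock, clean air against outside) and -0.20 (detoxification, low against clean air) came from the fit without replicate 1 of high exposure. They reflect fewer members and not the effect of an array in the comparison.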

Other observations

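The iron deficiency test and the family tests were chosen after the values were seen, and the ribosome biogenesis test was chosen for genes whose values had not been seen. Ribosome biogenesis genes were called higher in clean air than outside the chamber in 12 of 18 tested members, with a mean log2 difference of 1.27. Some of the 18 had been seen to rise here before the list was made, so that count and mean are no independent support. Among the 12 not seen before, 6 rose and the mean was 0.88: AT3G23620 by 1.11 ± 0.20 (SE), AT2G40360, a large-subunit assembly factor gene, by 0.99 ± 0.23 and AT3G05060, a nucleolar protein gene, by 0.93 ± 0.18. A hypothesis is that these genes rise together in the chamber. Over the unseen genes camera with an estimated correlation gave p = 0.0469 (adjusted p = 0.0704), so the test passed unadjusted and not adjusted. In low and high exposure against clean air 14 and 13 of 18 members rose (means 1.02 and 0.89). Of the 12 unseen genes 11 and 10 rose (means 0.98 and 0.96). With an estimated correlation neither set passed camera (adjusted p = 0.126 and 0.318).

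Iron deficiency genes were lower at high than at low exposure in 3 of 4 tested members and higher in 1 (mean -3.71). AT1G47400 and AT5G05250 were at least 60.9-fold and 43.7-fold lower, the transcription factor gene PYE fell by 2.52, and AT3G07720 was higher by 0.70. Of the low exposure arrays replicate 3 was highest in the first 3 genes, and without it they were at least 21.6-fold and 27.3-fold lower and PYE fell by 1.90. A joint fall was not shown: camera with an estimated correlation gave p = 0.38. Families named by a shared symbol stem were also tested. Of 13 serine carboxypeptidase-like (SCPL) genes 12 fell at high exposure against clean air (mean -1.25, camera adjusted p = 0.00154; adjusted p = 0.109 with an estimated correlation), among them scpl46 (-2.33), scpl35 (-2.24) and scpl50 (-1.95). This family had the lowest camera p of that comparison. The CML and PRA families also passed camera there at the preset correlation, upward (adjusted p = 0.0477 each). At low exposure against clean air 3 SCPL genes fell and 1 rose. Of 132 family tests 0 passed camera with an estimated correlation, adjusted, and 12 had an unadjusted p under 0.05. The 3' minus 5' control signal also moved with the high exposure arrays.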
